A study of Mus musculus with 4 samples.

How the data were processed

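RNA was sequenced from mouse microglia of the C57BL/6 strain grown in primary glial culture. Per the labels' protocols, cells were detached with trypsin, stained and sorted by flow cytometry into TRIzol LS, RNA was purified with a column kit and DNase, and libraries were made with the NEBNext Ultra II RNA kit. The antibodies and gates of the sort are not given in the sources used here. The 4 libraries form 1 group, cultured microglia, with replicate numbers 1 to 4 in the labels. Nothing in the labels says whether they came from separate cultures or animals, so every SD and p-value measures only the spread between these libraries, which may be technical. The series was designed to set these cells beside cultured hematopoietic stem and progenitor cells and beside co-cultures of such cells with glia; libraries of those groups were not analysed here, so no comparison between groups was made.

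The authors deposited whole-number read counts per gene symbol, with 1 file per library and no normalization. Per the submitters' processing notes, the tools were STAR 2.7.10a, SAMtools 1.16.1 and HTSeq 0.11.2, and the genome build was mm39 (GRCm39). The annotation release, the strand setting and the way overlapping genes were counted are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene may not have been told apart. Each file listed 56832 genes and 5 summary lines. The summary lines (reads on no gene, ambiguous reads, reads aligned to several places, and 2 lines at 0) held 11.8% ± 0.159 (SD, n = 4) of all reads listed and were left out of library sizes and tests. There were 0 columns that belonged to no sample.

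Library sizes were the summed gene counts, 27012285 in replicate 1, 23436924 in replicate 2, 23212183 in replicate 3 and 28469813 in replicate 4. A count of 0 in a library allows up to 3 counts, which is 0.105 to 0.129 CPM depending on the library (CPM, counts scaled to a common library total); this limit covers counting error only. To compare different genes, length-normalised values (TPM, counts divided by gene length and scaled to a common library total) were computed here from the deposited counts and the summed length of each gene's merged exons in GENCODE M21, matched by symbol. Of the listed symbols 89.1% matched, and they held 98.8% of the counts; of the 12966 genes with at least 10 counts in every library 97.1% matched. GENCODE M21 is on GRCm38, another build than the authors used, so it supplied lengths and gene types only and no coordinates are given. Where several annotated genes had 1 symbol, the longest was used. Exon length over all isoforms overstates the transcript length of genes with many isoforms, and so understates their TPM. In GENCODE M21, other genes overlap 34.4% of the exon bases of Ctsd and 68.7% of Itgam; a counting mode that discards ambiguous reads would understate such genes. Some listed genes are near-identical copies (Hba-a1 and Hba-a2, Hspa1a and Hspa1b) or related genes (H2-K1 and H2-D1, Ccl3 and Ccl4). Their values are uncertain to the extent that they share reads, because shared reads could be dropped.

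Before the data were examined, 27 lists of genes (377 different genes) were fixed for microglia, other myeloid and blood cells, the other cell types of a glial culture, and cell states, together with 12 comparisons between lists, their tests, the test of spread between libraries, the alternatives and the rule for the genes named. The technical explanations weighed in the closing section, and the tests of them, were chosen after the spread between libraries had been seen. That rule takes the 20 genes with the highest mean TPM, the 4 highest and 2 lowest members of every list, a fixed set of marker genes, any list member at 0 or under 1 TPM, and the 20 genes with the largest SD of log2 CPM among those past the spread test at a mean of at least 10 CPM. Genes named outside it are said to be so. Some genes that the rule takes are not reported here, though they stay in the lists and counts. For 1 list member an older symbol was matched after the data were seen. For each comparison between lists, the difference of the list medians of log2(TPM + 1) was taken in each library, leaving out genes on both lists, and tested with an exact two-sided sign-flip permutation test over the libraries. With 4 libraries the smallest p that test can give is 0.13, so no such comparison can pass 0.05, and the differences are given with their SD and range. As a description, the median of each list was placed among 10000 random lists of the same size drawn from protein-coding genes.

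Differences between the libraries were tested per gene in edgeR 4.0.16 (R 4.3.3) with a model of 1 mean per gene, TMM scaling, genes kept by filterByExpr and the trended dispersion. The deviance of each gene was compared with a chi-square distribution with 3 degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. This asks whether the libraries differ more for a gene than is typical of genes at its abundance. For lists, the median SD of log2 CPM (prior count 2) was placed among 10000 random lists matched on mean abundance in 20 bins; lists with fewer than 5 tested members were left out. The test was tried on simulated data with the real means and library sizes of the 12879 tested genes. Each simulated gene was drawn with the trended dispersion that the test assumes. The test recovered 77% of 100 genes raised 2-fold in 1 library and 97% of 100 genes raised 4-fold. It made 5 false calls there, and called 0 genes when nothing had been changed. Real genes scatter around the trend, so these figures do not give the error rate of the calls in the real data. Alternatives were other scalings (DESeq2 1.42.0 size factors, total counts), other filters, a common dispersion, DESeq2's dispersion outliers, CPM in place of TPM, pseudocounts of 0.1 and 10, means in place of medians, and leaving out each library in turn. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. For the technical tests, the trend of log2 deviations on exon length was removed per library with lowess (statsmodels 0.14.6). The labels give no batch or date.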

Results

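Gene expression was measured by RNA sequencing in 4 libraries of microglia, the resident macrophages of the brain, sorted from mouse primary glial cultures. In this series such cells are the endogenous reference for myeloid cells grown from blood progenitors in the presence of glia. The libraries held 27012285, 23436924, 23212183 and 28469813 gene counts in replicates 1 to 4, and 11704 genes were at 1 CPM or more in all 4, of which 10974 were annotated as protein-coding. Mitochondrially encoded genes took 1.11% ± 0.158 (SD, n = 4) of the counts, from 0.900% in replicate 3 to 1.24% in replicate 4. Ribosomal protein genes took 3.67% ± 0.169. Across the 12879 genes past the abundance filter, Pearson's r of log2 CPM between pairs of libraries lay between 0.987 and 0.993; this is across genes, which are not independent replicates. No files were identical, and no pair agreed within counting noise, with a chi-square of the counts of 5.57 to 15.02 times its degrees of freedom, so none was treated as 1 library deposited again; this does not show that they came from separate cultures.

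The labels give the sex as female, which was checked first. Xist, the RNA that coats the inactive X chromosome of female cells, was at 300.2 CPM ± 42.9 (SD, n = 4), with 5864 to 9699 counts per library. Transcripts of 4 Y-linked genes were also present in every library. Ddx3y, an RNA helicase gene, was at 36.2 CPM ± 5.44, the histone demethylase gene Kdm5d at 20.5 ± 0.742, the translation factor gene Eif2s3y at 18.8 ± 1.90 and Uty, named after its values were seen, at 10.5 ± 1.162. The lowest of these counts was 233, for Uty in replicate 2. Usp9y had 0 counts in all libraries, which allows up to 0.129 CPM in any 1 library, and Tsix, antisense to Xist, had 1 count in total. The sex-linked list had a median of 4.59 TPM ± 0.195.

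The most abundant transcript was Apoe, which encodes a lipid carrier, at 50092 TPM ± 1678 (SD, n = 4 here and for every value below). The 20 highest genes also included the iron-storage genes Ftl1 (18192 ± 1156) and Fth1 (4663 ± 139), lysozyme Lyz2 (15979 ± 849), the protease genes Ctsd (13831 ± 537) and Ctss (5097 ± 372), the protease inhibitor gene Cst3 (10967 ± 363), and the 3 chains of complement C1q, C1qa (12624 ± 261), C1qb (11747 ± 56.2) and C1qc (5270 ± 384). The Fc receptor-like gene Fcrls, used as a microglial marker, was at 5346 ± 18.0. Together the 20 genes with the most counts took 13.1% ± 0.137 of each library.

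The first set of comparisons asked how the microglial signature stood beside those of other myeloid and blood cells in the same libraries. Of 20 microglia-enriched genes, 18 were at 1 CPM or more in all libraries and 14 had a mean of at least 100 TPM. The list median was 259 TPM ± 14.98, above all 10000 random lists. Besides Fcrls, the fractalkine receptor Cx3cr1 was at 2311 ± 78.4 and the membrane protein gene Tmem119 at 1380 ± 79.96, while the purinergic receptor P2ry12 was at 278 ± 54.8. The transcription factor Sall1 was lower, at 9.26 ± 0.662. The lowest members were Crybb1, at 0.894 ± 0.306, and Siglech, a lectin gene, at 0.680 ± 0.486. All 20 genes shared by microglia and other macrophages were detected, with a list median of 1781 TPM ± 43.4. They included the growth factor receptor Csf1r (2830 ± 108), the lipid receptor Trem2 (778 ± 13.4), the transcription factor Spi1 (610 ± 16.7), Aif1 (470 ± 8.34), the integrin gene Itgam (212 ± 14.99) and, lowest, the leukocyte phosphatase Ptprc (67.5 ± 10.1).

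Genes of border-associated and other tissue macrophages were split. Of 15, 9 were detected in all libraries, led by the scavenger receptor Stab1 (752 TPM ± 51.1), Ms4a7 (527 ± 37.0), the chemokine Pf4 (309 ± 14.4) and the mannose receptor Mrc1 (295 ± 30.9). Cd163 and Lyve1 had 0 counts in every library, which allows up to 0.129 CPM in any 1 library, and F13a1 was at 0.284 ± 0.111. The list median was 22.6 ± 2.23, and the microglial list lay above it by 3.46 ± 0.0932 on the log2(TPM + 1) scale, in 4 of 4 libraries (exact two-sided sign-flip permutation test, p = 0.13, the smallest that 4 libraries can give). That difference was 1.21 when only genes at 1 CPM or more in at least 1 library were kept, and 2.05 on CPM without gene length. Monocyte genes had a median of 0.872 TPM ± 0.0981. Within that list S100a4 (65.2 ± 17.6), fibronectin Fn1 (57.1 ± 6.997), Itgal (42.0 ± 5.59) and S100a6 (26.5 ± 2.65) were highest, whereas Ly6c2, Plac8 and Cd177 had 0 counts and the chemokine receptor Ccr2 was at 0.997 ± 0.272.

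Genes of blood progenitors, the starting cells of the wider series, were mostly near the floor. Of 16, 11 were under 1 TPM and the median was 0.250 TPM ± 0.0453. The stem cell factor receptor Kit was at 0.619 ± 0.211, Flt3 at 0.0340 ± 0.0559, and Hoxa9 had 0 counts. The highest were the sialomucin Cd34 (50.4 ± 4.85), the transcription factor Tal1 (45.7 ± 2.64), the protein C receptor Procr (11.1 ± 1.86) and Meis1 (1.73 ± 0.375). Of 15 neutrophil genes, 14 were under 1 TPM and 9 had 0 counts in every library, Elane, Mpo, Ly6g and Fcnb among them; the exception was the cytokine receptor Csf3r, at 70.9 ± 3.20. No member of the lymphocyte list or of the mast, erythroid and megakaryocyte list was at 1 CPM in all libraries. Their highest members were Cd4 (0.916 ± 0.147) and Gp9 (0.803 ± 0.261), and the list medians were 0 and 0.0450 ± 0.0901 TPM. The microglial list lay above the monocyte list by 7.12 ± 0.150, above the progenitor list by 7.70 ± 0.0875 and above the neutrophil list by 8.02 ± 0.0828 on the log2(TPM + 1) scale, each in 4 of 4 libraries with an exact permutation p = 0.13. Because the lower lists sit near 0, these sizes depend on the pseudocount; with a pseudocount of 10 they were 4.63, 4.71 and 4.75. With only genes at 1 CPM or more in at least 1 library, which leaves few neutrophil genes, the last was 1.88.

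**Figure D1:**
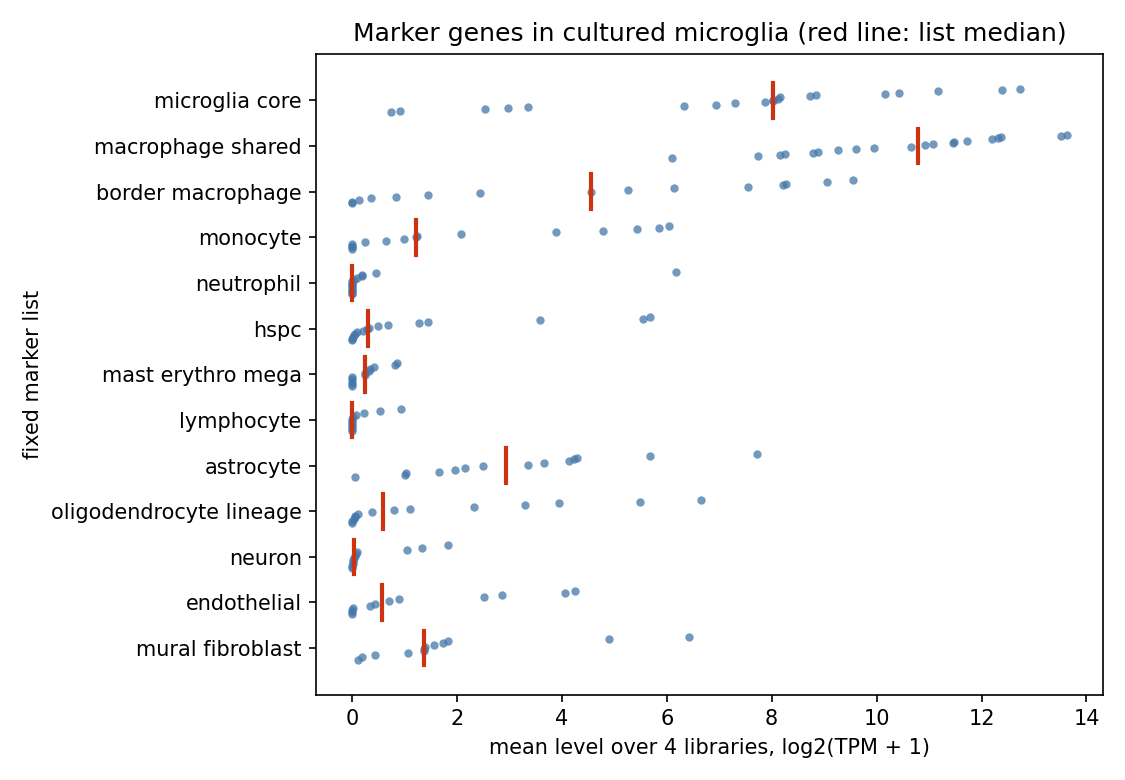
Mean level of each member of the 13 marker lists over the 4 libraries, on the log2(TPM + 1) scale; each point is a gene and the red line is the median of those points. The macrophage and microglial lists lie to the right, with medians of 1781 and 259 TPM, and the neutrophil and lymphocyte medians lie at 0.

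The next comparisons asked how high marker genes of the other cell types of a glial culture stood in the sorted cells. These levels cannot tell RNA carried over from other cells apart from expression by the microglia themselves. Of the lists compared here, astrocyte genes had the highest median. Of 14, 11 were detected in all libraries, with a median of 6.95 TPM ± 1.18. Clusterin Clu was at 210.5 ± 44.9, the intermediate filament gene Gfap at 50.3 ± 14.2, the water channel Aqp4 at 18.5 ± 1.51 and the glutamate transporter Slc1a3 at 17.8 ± 3.94. In the oligodendrocyte lineage list, with a median of 0.504 ± 0.0334, Cnp (99.3 ± 3.08), Mbp (43.9 ± 2.11) and Olig1 (14.4 ± 3.19) were well above Sox10 (0.0355 ± 0.0453) and Mog, which had 0 counts. The highest neuronal gene was Map2, at 2.53 ± 0.387, and the list median was 0.0256 ± 0.00660. Endothelial genes had a median of 0.487 ± 0.157, led by Flt1 (18.1 ± 0.839) and Slco1a4 (15.6 ± 3.30), with Pecam1 at 0.272 ± 0.0766. Genes of mural cells and fibroblasts had a median of 1.63 ± 0.425, led by the smooth muscle genes Acta2 (84.5 ± 21.2) and Tagln (28.7 ± 6.85). The shared macrophage list lay above the astrocyte list by 7.88 ± 0.281 on the log2(TPM + 1) scale, above the mural and fibroblast list by 9.41 ± 0.227, above the oligodendrocyte list by 10.2 ± 0.0109, above the endothelial list by 10.2 ± 0.128 and above the neuronal list by 10.8 ± 0.0326. The last 3 lists sit near 0, so these sizes depend on the pseudocount; with a pseudocount of 10 they were 7.41, 7.41 and 7.47. Each difference had the same sign in 4 of 4 libraries (exact permutation p = 0.13, the smallest possible). With only genes at 1 CPM or more in at least 1 library the order changed. The oligodendrocyte difference was then 7.19 and the astrocyte difference 7.30. The astrocyte list took 0.0439% ± 0.00925 of the counts and the shared macrophage list 3.07% ± 0.0229.

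Cell state genes were compared next. All 20 genes of the disease-associated microglia list were detected, with a median of 365 TPM ± 16.4. Apoe, Ctsd, Ctsb (3740 ± 181) and the secreted glycoprotein Spp1 (1314 ± 79.9) were highest, and Csf1 (18.1 ± 4.38) and Itgax (1.99 ± 0.215) lowest. The microglial list lay below this list by a small margin, a microglial minus disease-associated difference of -0.48 ± 0.0975 on the log2(TPM + 1) scale (4 of 4 libraries, exact permutation p = 0.13). It was -1.05 on CPM without gene length and -0.95 with means over list members. Lysosomal genes, all 20 of them above 100 TPM, had a median of 748 ± 12.2; Psap (4410 ± 209) was among the highest and Npc1 (120 ± 4.92) the lowest. Complement and Fc receptor genes had a median of 242 ± 22.8, with the Fc receptor Fcgr3 at 1029 ± 51.3. Genes of cholesterol and lipid handling had a median of 29.7 ± 2.86. In that list the lipid droplet gene Plin2 (703 ± 29.9), the efflux transporter Abca1 (609 ± 43.5) and the oxysterol enzyme Ch25h (575 ± 90.9) were above the synthesis gene Idi1 (3.12 ± 0.420).

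Genes of inflammatory mediators were present at uneven levels. The chemokines Ccl3 (254.5 TPM ± 114) and Ccl4 (232 ± 39.5), the cytokine Tnf (186 ± 92.0) and the inflammasome gene Nlrp3 (89.0 ± 4.71) were highest. Il1b was at 11.2 ± 2.20, and Il6 and Nos2, the inducible nitric oxide synthase, had 0 counts in every library. In the alternative-activation list Mrc1, Tgfb1 (236 ± 7.67) and Il4ra (212 ± 3.27) were followed by Il1rn (5.23 ± 0.334), while arginase Arg1 was at 0.0790 ± 0.123 and Chil3 had 0 counts. The inflammatory list, with a median of 11.8 ± 2.12, lay above the alternative-activation list, with a median of 0.325 ± 0.188, by 3.27 ± 0.114 on the log2(TPM + 1) scale (4 of 4 libraries, exact permutation p = 0.13). The direction turned when only genes at 1 CPM or more in at least 1 library were kept, to -3.51. It was 1.08 with a pseudocount of 10 and 1.13 with means over list members. Interferon-response genes were all detected, with a median of 28.5 ± 2.62, led by the antiviral membrane protein Bst2 (2544 ± 164).

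Antigen presentation genes of class I had a median of 124 TPM ± 8.79 and included B2m (4145 ± 423), H2-D1 (802 ± 46.8) and H2-K1 (527.5 ± 26.6). In the class II list, with a median of 5.04 ± 0.499, H2-DMa (95.05 ± 5.85) and the invariant chain Cd74 (55.5 ± 9.39) were highest. H2-Aa, an antigen-binding chain, was at 0.866 ± 1.02 and the class II regulator Ciita at 0.0293 ± 0.0409. Class I lay above class II by 4.40 ± 0.146 on the log2(TPM + 1) scale (4 of 4 libraries, exact permutation p = 0.13). All 20 cell division genes were detected, with a median of 12.8 ± 1.39; the replication clamp gene Pcna was at 153 ± 10.1 and Mki67, a marker of cycling cells, at 15.8 ± 4.34. In the list of growth factor receptors and ligands, with a median of 153 ± 6.79, Csf1r, Tgfbr2 (615 ± 12.6) and Ifngr1 (557 ± 17.7) were highest. The transcription factor list had a median of 56.5 ± 3.05, with Spi1, Cebpa (447 ± 17.7) and Irf8 (305 ± 8.77) among the highest and Tfec (1.14 ± 0.249) lowest.

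The last comparison was between the replicate libraries. Most genes varied little. The coefficient of variation between these libraries beyond counting noise was 10.3%, from the common dispersion, and it may be technical. The spread between libraries exceeded that of genes of like abundance for 143 of the 12879 genes tested (edgeR deviance test, trended dispersion, Benjamini-Hochberg adjusted p under 0.05), and 875 genes had an unadjusted p under 0.05. Of the 143, 68 were highest in replicate 1 and 60 were lowest there, and 45 were highest in replicate 3 and 54 were lowest there. In replicate 2 the numbers were 12 and 19, and in replicate 4 they were 18 and 10. Of all tested genes, on the same CPM without TMM scaling, 24.0% were highest and 35.3% lowest in replicate 1, and 30.2% were highest and 20.5% lowest in replicate 3. Without replicate 1 the count was 47, of which 36 were among the 143, and without replicate 3 it was 52. A common dispersion gave 532 genes, 81 of them shared, and DESeq2 marked 69 genes as dispersion outliers, all 69 among the 143. Of the 143, those lowest in replicate 3 included the mitochondrially encoded mt-Co1. Named after their values were seen, mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd4 and mt-Rnr2 were lowest there too.

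Immediate-early genes, which respond quickly to stimulation and to cell dissociation, stood out. Of 15 tested, 10 passed (10 also when adjusted over the list alone), and all 10 were highest in replicate 1; the list median over the libraries was 134 TPM ± 35.1. Egr1, an early transcription factor gene, was at 231 CPM in replicate 1 against 39.9 to 72.4 CPM in the other libraries (edgeR adjusted p = 2.4e-81). Fos was at 128 CPM in replicate 1 and at 53.7, 85.8 and 43.3 CPM in replicates 2, 3 and 4 (edgeR adjusted p = 2.1e-22), and Ier2 was at 129 CPM against 49.8 to 73.1 (edgeR adjusted p = 7.4e-20). Of 12 inflammatory genes tested, 4 passed (7 when adjusted over the list alone), and these 4 were also highest in replicate 1. Tnf was at 152 CPM there against 53.5 to 83.3 (edgeR adjusted p = 1.0e-20) and the chemokine Ccl2 at 53.6 against 10.2 to 20.5 (edgeR adjusted p = 1.6e-28); the others were Ccl3 and Ccl7, the last named after its values were seen. Without replicate 1, 3 immediate-early and 2 inflammatory genes passed.

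Astrocyte genes went the other way. Of 12 tested, 3 passed (5 when adjusted over the list alone), and all 3 were lowest in replicate 1. Gfap was at 39.8 CPM in replicate 1 and at 77.3, 76.9 and 56.9 CPM in replicates 2, 3 and 4 (edgeR adjusted p = 9.9e-06). Clu was at 152 CPM in replicate 1 against 207 to 262 CPM (edgeR adjusted p = 0.00021), and Slc1a3 was the third. Without replicate 1, 0 astrocyte genes passed. The 6 tested endothelial genes moved with them: their median deviation in replicate 1 was -0.35 on the log2 scale, beside -0.45 for the astrocyte list, although 0 of these 6 genes passed (3 over the list alone, 3 at an unadjusted p under 0.05). The median of all 12 listed endothelial genes, which lies near the floor, was instead highest in replicate 1, at 0.612 TPM. It was lowest in replicate 4, at 0.258 TPM. In the microglial list 2 of 18 tested genes passed (3 over the list alone), and 1 passed without replicate 3 or without replicate 4. With a common dispersion in edgeR 0 passed. P2ry12 was at 236, 185, 164 and 249 CPM in replicates 1 to 4 (edgeR adjusted p = 0.0010). Sparc, named after its values were seen, is also an astrocyte product and was at 188, 288, 322 and 251 CPM (edgeR adjusted p = 0.00013). In 5 other lists 1 gene each passed, among them Acta2, Mki67 and, named after their values were seen, H2-Eb1 and Egr2. Without replicate 3 the count was 0 in the mural and fibroblast, class II, cell division and complement lists, but 1 in the transcription factor list. Without replicate 1 the count was 0 in the complement and transcription factor lists, 1 each in the class II and cell division lists, and 2 in the mural and fibroblast list. With a common dispersion it was 0 in the complement list, 4 in the mural and fibroblast list and 2 in the transcription factor list. Adjusted over the list alone, 5 mural and fibroblast genes and 2 cell division genes passed, and 1 gene each in the class II, complement and transcription factor lists. No gene passed among 20 shared macrophage genes (2 over the list alone, 2 at an unadjusted p under 0.05, and 1 over all genes without replicate 1) or among 20 lysosomal genes (0 over the list alone, 0 unadjusted). The median SD of log2 CPM was 0.0471 in the shared macrophage list, at the 1.96th percentile of abundance-matched random lists (11.49 without replicate 2 and 4.71 without replicate 3), and 0.405 in the immediate-early list, above all of them. By the same measure the microglial list was at the 97.45th percentile (91.33 without replicate 3). Such a place was not particular to it. The mural and fibroblast list was at 99.67 (56.92 without replicate 3), the monocyte list at 98.3 (57.2 without replicate 1) and the disease-associated list at 97.25 (43.08 without replicate 3). The lysosomal list was at 38.2 and the growth factor list at 2.05. The astrocyte and inflammatory lists were at the 100th (84.27 and 96.72 without replicate 1). In the other lists with tested members no gene passed over all genes; adjusted over the list alone, 2 disease-associated genes passed, 1 gene each in the cholesterol, growth factor and sex-linked lists, and 0 in the border macrophage, monocyte, neutrophil, progenitor, lymphocyte, oligodendrocyte, neuronal, alternative-activation, interferon and class I lists.

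**Figure D2:**
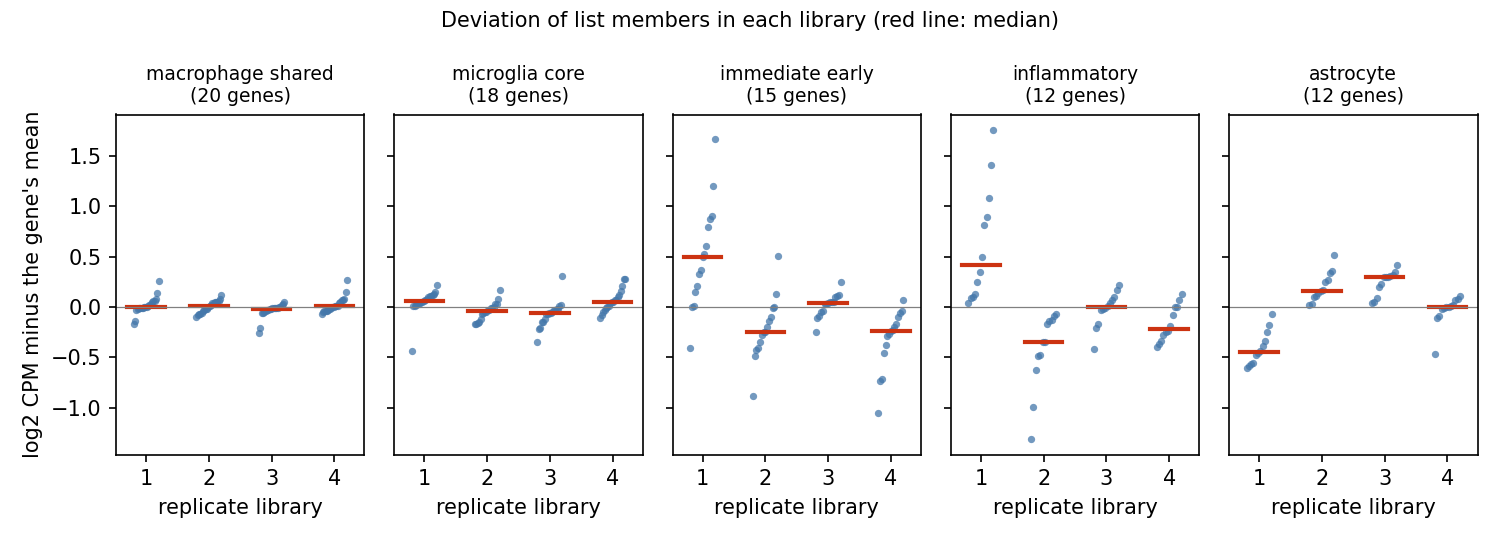
Deviation of each tested list member from its own mean, in log2 CPM, in replicate libraries 1 to 4 for 5 lists; each point is a gene and the red line is the list median. In replicate 1 the immediate-early median lies at 0.49 and the inflammatory median at 0.42, the astrocyte median at -0.45, and the shared macrophage median near 0 in every library.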

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

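Over the 4 libraries, 188 values (library summaries, list shares, list comparisons and named genes) were examined for a library standing apart from the others by Dixon's criterion, and 9 met it. Chance gives 9.4 for values not selected for spread, but the named genes include 20 taken for their spread, Egr1, Scd1 and Rgs1 among them, so the counts cannot be set against each other. Of the 9, 8 were in replicate 1. The test of the astrocyte list against the replicate 1 pattern was chosen after its value had been seen.

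Replicate 1 was low in the share of ambiguous reads, 1.99% against 2.26% to 2.31% in the others, and low in Tyrobp, at 802 CPM against 950 to 967. It was high in the share of counts on cell division genes, 0.0713% against 0.0604% to 0.0621%, and in Mcm3, at 89.1 CPM against 77.5 to 78.8. It was also high in Nr4a1, at 2.33 CPM against 0.948 to 1.12, in Egr1, at 231 CPM against 39.9 to 72.4, in the fatty acid desaturase Scd1, at 75.3 CPM against 17.1 to 22.1, and in the G-protein regulator Rgs1, at 81.1 CPM against 24.8 to 31.1. Replicate 4 was high in the difference between the shared macrophage and endothelial lists, 10.43 against 10.16 to 10.21 on the log2(TPM + 1) scale.

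Of the tested genes, 12 of 15 immediate-early and 9 of 12 inflammatory ones were highest in replicate 1, where the median deviation of all 27 from their own 4-library means was 0.49 on the log2 scale. Of all tested genes, on the same TMM-scaled values, 29.7% were highest there. The rise was not particular to both lists, since 15 of 20 cell division genes were highest there too, with a smaller median deviation of 0.16. A transcript-length trend between libraries exists, with a median deviation in replicate 1 of -0.07 for the 10% of genes with the shortest exon length and 0.05 for the 10% with the longest. Removing it left the median of both lists at 0.51, which argues against length as the cause. More RNA of other glial cells in replicate 1 is argued against for astrocytes, whose list had a median deviation there of -0.45, and the oligodendrocyte list was at -0.14; the mural and fibroblast list was at 0.32, but 4 of its 9 members were lowest there and 1 highest, and its most abundant gene, Acta2, was lowest at 42.8 CPM against 45.7 to 73.5, so the list decides nothing. A stronger response to culture, detachment or sorting may be the source and stays open too, since the labels record no handling difference and no biological explanation was tested.

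Astrocyte genes were lowest in replicate 1, which a varying share of astrocyte RNA could give although the cells were sorted; the most abundant list members were Clu at 210.5 TPM and Gfap at 50.3 TPM, and none of the 14 is on another list. In a further set of 30 astrocyte genes, chosen after the genes past the spread test were known and holding 0 of them, 60% of the 25 tested were lowest in replicate 1, against 30.7% of all tested genes on the same TMM-scaled values. Leaving out the genes past the test, which include other astrocyte genes, lowers that share, so it decides nothing and astrocyte RNA cannot be told apart from other sources by it. Among the genes past the test, and named after their values were seen, Mt3 was at 37.9 CPM in replicate 1 against 65.8 to 105. Hepacam was at 7.85 CPM there against 12.6 to 18.4, and Mlc1 at 55.2 against 77.2 to 102. They were picked from the 143 genes, of which 60 were lowest in replicate 1, so they decide nothing either. A transcript-length trend between libraries is argued against, since the list's median deviation was -0.45 before and -0.44 after its removal. Astrocytes caught in the sort, RNA taken up by the microglia and expression by the microglia stay open, and no biological explanation was tested.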

How the results depend on the processing

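The list comparisons kept their direction in 107 of 108 recalculations; the exception was the inflammatory list against the alternative-activation list, at -3.51 with only genes at 1 CPM or more in at least 1 library, where fewer genes near 0 enter the second list. The count of 143 genes with excess spread became 532 with a common dispersion and 69 as DESeq2 dispersion outliers, all 69 among the 143; leaving out each library in turn gave 47 to 118 (47 without replicate 1, 52 without replicate 3), with fewer libraries tested. Across these settings, 5 stayed within 1.5 times the reported count: both other scalings, the looser filter, and leaving out replicate 2 or replicate 4. The genes called were not always the same. Of the 143, 112 were also called with the looser filter, 130 with total counts and 143 with DESeq2 size factors. Without replicate 2 the overlap was 118, and without replicate 4 it was 100. The count of detected genes did so under all 7 of its alternatives. Of the descriptive percentiles, 38 for list levels moved and 16 did not, with CPM in place of TPM or random lists drawn from detected genes; 37 for list spread moved, all on leaving out a library, and 101 did not. No paired analysis was possible because all libraries belong to 1 group. No comparison of lists can pass 0.05 with 4 libraries, and a count of 0 in a library does not exclude a level there of up to 0.105 to 0.129 CPM, depending on its depth.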

Other observations

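Genes of several sensing and adhesion families were also looked at, and some of their members are on the lists. These families, the Xist test and the X and Y count ratios were chosen after the values had been seen. Under 1 TPM were 3 of 7 P2X, 3 of 8 P2Y, 9 of 18 integrin alpha and 2 of 8 integrin beta genes. Of 12 Toll-like receptor genes, 9 were at 1 CPM or more in all libraries. Tlr2, a sensor of bacterial lipoproteins, was highest, at 472 TPM ± 15.2 (SD, n = 4 here and below), followed by the endosomal receptors Tlr13 (385 ± 27.6), Tlr7 (197 ± 26.3) and Tlr9 (128 ± 9.14), with Tlr4 at 44.0 ± 7.47. Of the nucleotide receptors, P2ry6 (424 ± 9.75) and P2ry13 (261 ± 17.8) lay near P2ry12 (278 ± 54.8), and the ion channels P2rx7 (80.2 ± 1.63) and P2rx4 (78.6 ± 3.99) were the highest P2X genes. Of 22 chemokine receptor genes 16 were under 1 TPM; after Cx3cr1 the highest were Cxcr4 (260.2 ± 15.3) and Ccr1 (143 ± 19.5).

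Among integrins the beta chain Itgb5 stood at 2172 TPM ± 71.9, above Itgb2 (678 ± 33.1), the partner of Itgam, and Itgb1 (526 ± 19.2); of the alpha chains Itga6 (256 ± 15.3) was highest. All 11 semaphorin receptor genes were detected, led by Plxnb2 (589 ± 27.0) and Nrp1 (126 ± 9.62). While Siglech was at 0.680 ± 0.486, the highest genes of the sialic acid receptor family were Cd33 (132 ± 7.16) and Siglece (104 ± 13.1).

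Y-linked transcripts stood beside Xist in libraries labelled female. The counts of Ddx3y were 8.07% ± 0.645 of those of its X-linked relative Ddx3x, Kdm5d 13.2% ± 0.733 of Kdm5c, Eif2s3y 22.3% ± 1.91 of Eif2s3x and Uty 24.1% ± 2.23 of Kdm6a, with little difference between the libraries. Reads of the X-linked copies placed on the Y genes are argued against: in GENCODE M21 transcripts at most 0.140% of the 50-base windows of an X-linked copy occur in its Y-linked partner, far below the count ratio in 4 of 4 pairs. Libraries wholly from males under a wrong label are argued against by Xist, whose lowest value was 252.6 CPM. Cultures that pooled animals of both sexes may be the source, and so may cross-talk from libraries of male cells; neither was tested, and the labels name only females.

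Several of the most uneven genes lay outside the lists and were named after their values were seen or by the spread rule. Fabp4, a fatty acid binding protein gene, was at 23.6 CPM in replicate 1 and at 1.37 to 1.65 in the others. Rps29, a short ribosomal protein gene, was at 179 CPM in replicate 1 against 410 to 459. Further ribosomal protein genes past the test were lowest in replicate 1 too. Rps28 was at 128 CPM there against 234 to 269, and Rpl38 at 104 against 170 to 182. The others were Rpl35a, Rpl37 and Rpl39. The Spearman correlation across 12503 genes between exon length and the deviation in a library was 0.165 in replicate 1 and -0.102 in replicate 3; genes are not independent replicates.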
